A study of Mus musculus with 2 samples.

How the data were processed

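The 2 libraries of polyadenylated RNA from G1E-ER4 cells exposed to 17beta-estradiol at 10 nM over 24 h formed 1 group with n = 2. Replicate numbers are those of the labels, and no sample was left out.

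Per the deposited descriptions of the files, reads were placed on assembly mm10, and each library came with gene and transcript tables for the GENCODE releases M21 and M4, made from an alignment to the transcriptome, and with a transcript table for M21 made from the reads themselves. The aligner and the quantifiers are not given in the sources used here. The column names of the first tables are those RSEM writes, and those of the table made from reads are those kallisto writes. The deposited expected counts are the authors' estimated fragments per gene or transcript, not normalized and not always whole. The authors' TPM values, per the file headers, are abundances scaled to a fixed total over all entries of each table, given as a maximum likelihood and as a posterior mean estimate. The other deposited columns hold the authors' lower and upper bounds of an interval for the posterior TPM, whose level is not given in the sources used here, and the effective length in bases. The deposited percent column gives each transcript's part of its gene's TPM, and shares of transcripts were computed here from TPM. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes may share reads.

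The M21 gene table was the main table by a rule fixed before the data were examined, since it has the later annotation. All 55536 of its mouse gene identifiers matched GENCODE M21 with their version, and coordinates are from that annotation on mm10. Of 43346 gene identifiers in the M4 table, 42462 matched M21 without version. Spike-in and tRNA entries were left out. Of 298 list entries, 289 were found in the main table and 9 were not, among them Hbb-b1, Hbb-b2 and Ahsp.

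A gene was called detected at 1 TPM or more in both replicates. List levels are medians of log2(TPM + 1), with a pseudocount of 1, and were set against 10000 random lists of protein-coding genes of the same size. Shifts between replicates are medians of the log2 ratio of TPM + 1 over protein-coding members at 1 TPM or more in either replicate, which leaves out Rn7sk, Rmrp and Rpph1. They were set against 10000 lists of protein-coding genes matched in 20 bins of mean expression, for the 16 lists with at least 3 such members. Genes over 2-fold apart were counted among those with a mean expected count of at least 50, and 20 Poisson simulations drew both libraries at their own depth from pooled proportions. The GC content of a gene is the mean over its M21 transcripts, known for 21951 of 22028 protein-coding genes, and its trend was removed as the median in 20 bins. A floor of 3 counts was used for genes at 0, and the intervals are at 95%. Intervals and floors cover counting error only.

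Named genes followed a rule fixed before the data were examined: Gata1, Gata2, Kit, Klf1, Esr1 and every globin gene; the 3 detected members of each list with the highest mean TPM and the lowest 1 or 2 undetected; markers of other lineages at a mean of 10 TPM or more; the 10 most abundant genes; the 5 protein-coding genes furthest apart between replicates in each direction; and 12 genes for transcripts. A few genes that this rule names are not reported here. The lists cover adult and embryonic globins, heme synthesis, iron handling, the red cell membrane, erythroid transcription factors, late erythroid and early progenitor genes, the cell cycle, 6 sets of markers of other cell types, steroid receptors, estrogen-responsive, stress, interferon, glycolysis, housekeeping and poorly polyadenylated genes.

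With 1 group no test between conditions was possible. The code that counts such genes was tested on simulated data for the 9029 genes compared, with counting error only and none of the further spread between these libraries: of 200 genes raised in replicate 2, 200 were recovered at 3-fold with 1 false call and 200 at 4-fold with 3 false calls. Alternatives were the M4 table, the table made from reads, TPM over nuclear protein-coding genes, posterior means, other pseudocounts and thresholds, counts scaled to library size (CPM), edgeR TMM scaling and DESeq2 size factors on rounded expected counts, and each replicate alone. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

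The depth differed 5.06 times between the libraries, 71485617 against 14121747 expected counts, so values of replicate 2 carry more counting error.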

Results

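Polyadenylated RNA was sequenced with paired-end reads from G1E-ER4, a mouse erythroid line derived from Gata1-null cells in which GATA1 function is restored through a fusion protein that estradiol activates. The cells had been exposed to 17beta-estradiol at 10 nM over 24 h, which induces erythroid differentiation in this line. The series held 1 group with 2 libraries, numbered in the labels as biological replicates 1 and 2. Both libraries share 1 biosample record in the labels, and nothing there says that they came from separate cultures, so the spread between them may be technical. The expected counts per gene summed to 71485617 in replicate 1 and 14121747 in replicate 2, a ratio of 5.06. There was no untreated or parental sample to compare with, so the values below are levels in treated cells, not changes, and no p-value between conditions is given. The question the design answers is which genes the treated cells held at high, low or undetectable levels, and how closely both libraries gave the same answer.

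Gata1, the erythroid transcription factor that the line lacks at its endogenous locus and regains through the fusion, was at 2890 TPM in replicate 1 and 2661 TPM in replicate 2, a mean of 2776 ± 162 TPM (SD, n = 2). The authors' own interval of the posterior estimate ran from 2844 to 2863 TPM in replicate 1 and from 2476 to 2518 TPM in replicate 2, and both maximum likelihood values lay above it. Gata1 (ENSMUSG00000031162.14) lies on chromosome X from 7959260 to 7978071 on the minus strand of mm10, and these gene-level values cannot separate transcripts of the fusion from those of the locus. In the table quantified from reads Gata1 was at 2112 and 487 TPM, and at 2850 and 2045 TPM once that table was rescaled over nuclear protein-coding genes. Gata2, a factor of earlier progenitors whose gene GATA1 is known to repress, was at 77.0 and 184 TPM, or 131 ± 76.0 TPM (SD, n = 2). The Gata1 to Gata2 ratio was 37.6 in replicate 1 and 14.4 in replicate 2, against 79.8 and 37.0 with annotation M4 and 21.6 and 7.88 in the table quantified from reads. Kit, the stem cell factor receptor, was at 0.92 and 0.61 TPM, below the detection threshold of 1 TPM in both, but the authors' intervals for the posterior, 0.905 to 1.31 TPM and 0.73 to 2.51 TPM, reach above it. Klf1, an activator of adult beta globin, was at 634 and 2134 TPM, and Esr1, the mouse estrogen receptor alpha gene, had 0 counts in replicate 1 and 1 count in replicate 2.

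Globin transcripts were almost entirely of the adult kind. Hbb-bs, an adult beta globin gene on chromosome 7 from 103826534 to 103828096, had the highest mean level of all genes, at 97719 and 34786 TPM or 66252 ± 44501 TPM (SD, n = 2). It was the highest gene in replicate 1, while the ferritin gene Fth1 at 47326 TPM was the highest in replicate 2. Hba-a1 was at 67200 and 30385 TPM, Hba-a2 at 32217 and 5102 TPM, and Hbb-bt at 1294 and 88.2 TPM. Hba-a1 and Hba-a2 are near-identical copies, so their split is uncertain, and the share and ratio below use their sum. All globin genes together held 19.8% of TPM in replicate 1 and 7.04% in replicate 2, a mean of 13.4% ± 9.06 (SD, n = 2). As a share of expected counts this was 8.49% (95% Wilson interval 8.48% to 8.50%) and 3.19% (3.18% to 3.20%), intervals that cover counting error only. The alpha to beta globin ratio in TPM was 1.00 in replicate 1 and 1.02 in replicate 2, or 1.01 ± 0.00954 (SD, n = 2). In expected counts, without correction for length, it was 0.772 and 1.10, and in the table quantified from reads 0.664 and 0.340, so the closeness of both replicates did not hold in these units.

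Embryonic globins were near the detection limit. Hba-x was at 3.83 and 3.38 TPM, Hbb-y at 3.33 and 2.25 TPM, and Hbb-bh1 at 2.87 and 2.18 TPM, on 13 to 134 expected counts per library. Hbq1b was at 1.43 and 3.91 TPM and Hbq1a at 0.04 and 0 TPM. Hbb-bh2 and the pseudogene Hbb-bh0 had no counts in either library. The embryonic genes made up 0.00626% of beta-like globin TPM in replicate 1 and 0.0127% in replicate 2, against 0.00973% and 0.0413% by the posterior mean TPM.

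Of 22028 protein-coding genes, 7297 reached 1 TPM in both replicates, 8171 in replicate 1 and 7614 in replicate 2. Of the 23 gene lists fixed before the data were examined, 12 had a median at or above the 95th percentile of 10000 random lists of the same size in both replicates. These random lists were drawn from all protein-coding genes, most of which were not detected, so a list of expressed genes passes easily. The 12 took in both cell cycle lists and the stress, glycolysis, housekeeping and poorly polyadenylated lists beside erythroid ones. Passing is therefore not particular to erythroid genes.

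Erythroid groups were at high levels. Among 15 erythroid transcription factors, 14 were detected and 12 were at 100 TPM or more in both replicates. The highest was Zfpm1, the GATA1 cofactor FOG1, at 2283 and 4616 TPM, followed by Gata1 and Klf1. Lmo2 and Tal1, which join GATA1 in a DNA-binding complex, were at 675 ± 211 and 460 ± 119 TPM (SD, n = 2). Nfia was not detected, at 0.04 and 0.06 TPM. All 11 heme synthesis genes were detected, with a list median of 250 TPM in replicate 1 and 135 TPM in replicate 2. Alad, which forms porphobilinogen, was at 798 ± 606 TPM, the transporter gene Abcb10 at 533 ± 177 TPM, and Fech, which inserts iron into protoporphyrin, at 458 ± 60.7 TPM (SD, n = 2 each). Alas2, the erythroid enzyme of the first step, was at 304 and 69.0 TPM, a ratio of 2.19 in CPM.

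Of 14 iron handling genes, 13 were detected. The ferritin genes Fth1 and Ftl1 led the list at 39153 ± 11558 and 37447 ± 3687 TPM, and Pcbp1, an iron chaperone gene, was at 2583 ± 2095 TPM (SD, n = 2 each). Ireb2 was below 1 TPM in replicate 2, at 0.2 TPM. Of 18 red cell membrane genes, 16 were detected. Sptb, the erythroid beta spectrin, was at 741 ± 308 TPM, the anion exchanger gene Slc4a1 at 605 ± 170 TPM and the ankyrin gene Ank1 at 407 ± 73.7 TPM (SD, n = 2 each). Epb42 was below 1 TPM in replicate 2, at 0.26 TPM, and Aqp1 had no counts in either library. Of 17 other late erythroid genes, 14 were detected, led by Blvrb at 3218 ± 780 TPM, Car2 at 732 ± 94.4 TPM and the catalase gene Cat at 408 ± 90.8 TPM (SD, n = 2 each). Alox15 and Trim58 had no counts in either library.

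Early progenitor genes were mixed. Of 18, 10 were detected, and the highest were Hhex at 80.7 and 403 TPM, Runx1 at 149 and 279 TPM, and Gata2. Cd34 and Ets1 had no counts. The list median lay at the 93.5th percentile of random lists in replicate 1 and the 97.9th in replicate 2, so its side of the 95th percentile depended on the replicate.

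All 17 proliferation genes were detected. Mcm2, part of the replicative helicase, was at 804 ± 174 TPM, the cyclin A gene Ccna2 at 512 ± 25.0 TPM, and Rrm2 at 272 ± 199 TPM (SD, n = 2 each). Among 12 cell cycle inhibitors and D cyclins, 8 were detected, led by Ccnd3 at 1688 ± 148 TPM, Gadd45a at 150 ± 122 TPM and Cdkn1b at 134 ± 15.3 TPM (SD, n = 2 each). Ccnd1 and Cdkn1c had no counts.

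Markers of other lineages were close to absent. None of the 10 mast cell and basophil, 15 granulocyte and monocyte, 14 lymphoid, 11 pluripotency or 12 stromal and endothelial markers was detected, and all 11 pluripotency markers, Dppa3 and Dppa5a among them, had no counts in either library. The highest mean level was 0.99 TPM among lymphoid markers, close to the threshold, and 0.645 TPM among mast cell and basophil markers. Only 4 of the 14 lymphoid markers had no counts in both libraries. A count of 0 allows up to 3 counts, which is 0.042 CPM in replicate 1 and 0.212 CPM in replicate 2. Cpa3 and Cma1 of mast cells, Cebpa and Cebpe of granulocytes, and Dcn of stroma had no counts. The T cell genes Cd3g and Cd4 and the collagen gene Col3a1 were listed at 0 TPM in both, on at most 1 count. The exceptions were megakaryocyte markers, of which 3 of 14 were detected. Gp1ba was at 16.5 and 28.8 TPM, Itga2b at 3.17 and 2.96 TPM, and Gp9 at 1.87 and 3.56 TPM, while Pf4 and Gp6 had no counts. The median log2(TPM + 1) of the joined heme synthesis, membrane and late erythroid lists exceeded that of the joined granulocyte and monocyte, lymphoid, pluripotency and stromal lists by 6.73 in replicate 1 and 6.58 in replicate 2, or 6.66 ± 0.11 (SD, n = 2). The median of the latter was 0 in both, so the pseudocount sets the size of this difference, which was 9.96 with a pseudocount of 0.1.

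**Figure D1:**
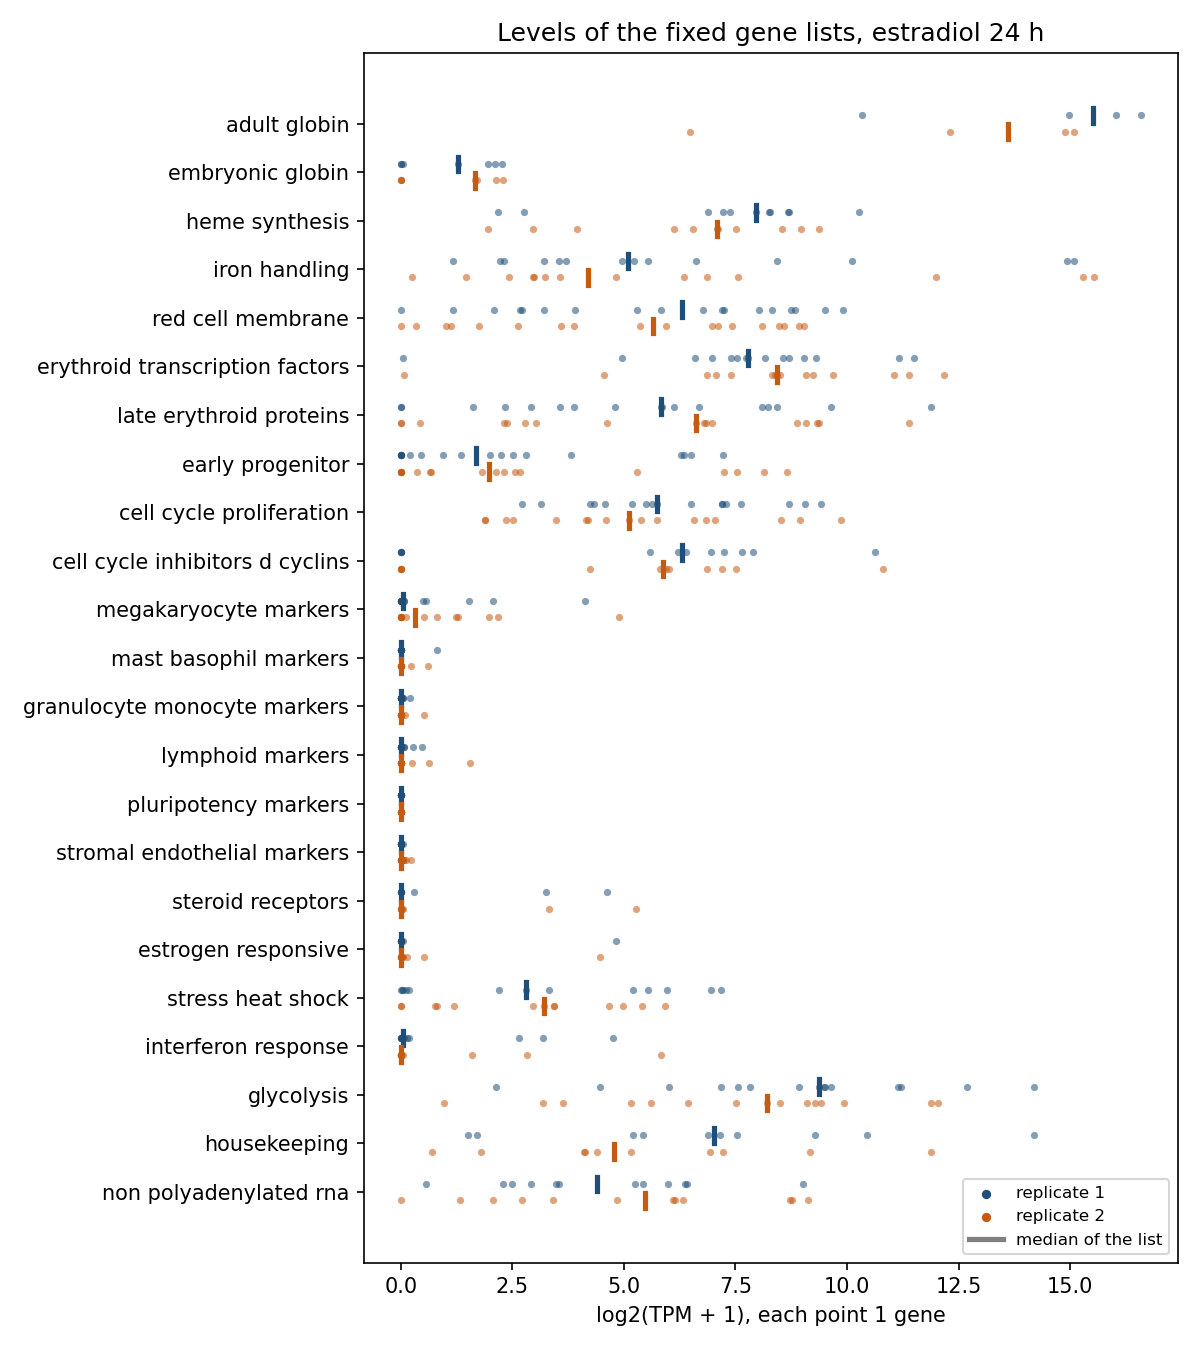
Each point is 1 gene of a fixed list, with log2(TPM + 1) on the horizontal axis and replicates 1 and 2 in separate rows and colours, and each vertical bar is the median of the list in that replicate. Adult globin genes lie at the top of the scale and the 11 pluripotency markers all at 0.

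Steroid receptor and estrogen-responsive genes were mostly undetected. Of 8 receptor genes, Esrra at 30.6 ± 9.84 TPM and the glucocorticoid receptor gene Nr3c1 at 8.76 ± 0.29 TPM (SD, n = 2 each) were detected, and Esr2 had no counts. Of 10 genes that estrogen is known to regulate in other tissues, 1 was detected, Xbp1 at 24.4 ± 4.44 TPM, and Areg had no counts. Of 12 interferon-response genes, 3 were detected, among them Irf7 at 25.9 and 56.3 TPM and Bst2 at 5.26 and 2.02 TPM, a ratio of 5.36 in CPM, and Ifit1 and Ifit3 lay at or near 0. Of 13 stress genes, 8 were detected. Ddit3 was at 145 and 24.4 TPM, Hsp90aa1 at 124 and 9.89 TPM, a ratio of 3.29 in CPM, and Dnajb1 at 45.8 and 59.6 TPM. Atf3 had no counts and Hspa1a was at 0.02 and 0 TPM.

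Of 15 glycolysis genes, 14 were detected, led by Gapdh at 18561 and 3745 TPM, Aldoa at 6626 and 4209 TPM, and Gpi1 at 2272 and 973 TPM. Hk2 was at 3.39 and 0.96 TPM. Of 10 housekeeping genes, 9 were detected, with Actb at 1397 and 576 TPM, Rplp0 at 623 and 147 TPM, and Hprt below the threshold in replicate 2 at 0.63 TPM. Among 12 measured RNAs that largely lack a poly(A) tail, 11 were detected. Rn7sk was at 514 and 556 TPM, Rpph1 at 84.5 and 432 TPM, Rmrp at 62.2 and 420 TPM, and Hist1h1a at 0.49 and 0 TPM.

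The 10 genes with the highest mean TPM were Hbb-bs, Hba-a1, Fth1, Ftl1, Hba-a2, Ptma, Rplp1, Hist1h2ap, Gm42418 and Gm26917. Ptma was at 7868 and 23808 TPM, a ratio of replicate 2 over 1 of 1.19 in CPM, Rplp1 at 15576 and 14720 TPM, and the histone gene Hist1h2ap at 22719 and 7318 TPM. Gm42418 and Gm26917, neighbours on chromosome 17 that are annotated as long noncoding genes, were at 8839 and 17543 TPM and at 4612 and 19176 TPM. The source of the reads placed on them was not tested, so these values need not reflect expression of long noncoding RNA. The ferritin, Ptma, Rplp1, Gapdh and histone genes have close copies or processed pseudogenes, so their levels depend on how reads were shared among copies.

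The replicates differed by more than counting error. Across 8488 protein-coding genes at 1 TPM or more in either replicate, log2(TPM + 1) correlated with Pearson's r of 0.846 and Spearman's rho of 0.830, a correlation across genes, which are not independent replicates. Of 9029 genes with a mean expected count of at least 50, 4600 (50.9%) were over 2-fold apart in TPM, 1401 higher and 3199 lower in replicate 2. Poisson counting error alone gave at most 18 such genes in 20 simulations. The median log2 ratio of replicate 2 over 1 was -0.39. With that median set to 0, the split became 2134 higher and 2473 lower, and in CPM, without length correction, it was 873 higher and 3731 lower around a median of -0.64. The filter uses raw counts and replicate 1 was deeper, so it admits genes low in replicate 2 more readily. Without a count filter, on TPM + 1, 1436 genes were higher and 2749 lower. In the table quantified from reads 7922 genes were over 2-fold apart, 466 higher and 7456 lower, and once it was rescaled over nuclear protein-coding genes, and counted over those alone, 3421 were, 1485 higher and 1936 lower. A comparison of 1 library with 1 other has no replicate check, so it describes these libraries only.

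Glycolysis and housekeeping genes stood apart between the replicates. The call for adult globin genes depended on whether the alpha genes were summed and, if summed, on the alternative used. All 4 measured adult globin genes were lower in replicate 2, with a median log2 ratio of -2.07, at the 0.26th percentile of 10000 random lists matched on mean expression. Hbb-bs, Hba-a1 and Hba-a2 are among the 10 most abundant genes, so most genes in their bin of 20 lay at lower levels. The match is therefore loose for globin genes, taken singly or summed. With Hba-a1 and Hba-a2 summed into 1 member, the median was -1.49 at percentile 3.61, within the central 95% of random lists. The median lay below them in 4 of 8 alternatives, with percentiles from 1.1 to 3.74 over all 8. That list holds 3 members, the minimum for this comparison. Hbb-bs and Hbb-bt, at -1.49 and -3.86, stayed separate members, and sharing of reads between these 2 beta genes was not examined. Of 15 glycolysis genes, 14 were lower in replicate 2, with a median of -1.26 at percentile 0.1. Of 10 housekeeping genes, Gapdh among them as in the glycolysis list, 9 were lower, with a median of -1.29 at the 0.54th percentile. The medians of these 3 lists stayed negative under all 8 alternative settings tried. The other 13 lists tested, the poorly polyadenylated one on only its 8 protein-coding members, lay within the central 95% of random lists. Of these, the early progenitor list came closest to the bound, with a median of 0.61 at the 97.46th percentile, 7 of its 10 members being higher in replicate 2. It lay outside under 7 of 8 alternatives, and in the unscaled table quantified from reads, where most genes were lower in replicate 2, its median was -0.66 at percentile 98.83. Heme synthesis genes had a median of -0.23 at the 23.8th percentile, and lay below the central 95% in 3 of 8 alternatives, at -0.63 with TMM, -0.55 with DESeq2 and -0.98 in CPM. Proliferation genes, at -0.76 and percentile 4.3, lay below it in the same 3. Megakaryocyte markers, at 0.67 and the 96.9th percentile, lay above it in those 3 and with annotation M4. TMM, DESeq2 and CPM all use counts without length correction and differ by 1 factor per library. They therefore count as nearly 1 alternative, here and among the 4 for the summed globin genes. Erythroid transcription factors had a median of 0.59 at the 73.9th percentile, which became -0.03 at percentile 36.7 with the trend on GC content removed.

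**Figure D2:**
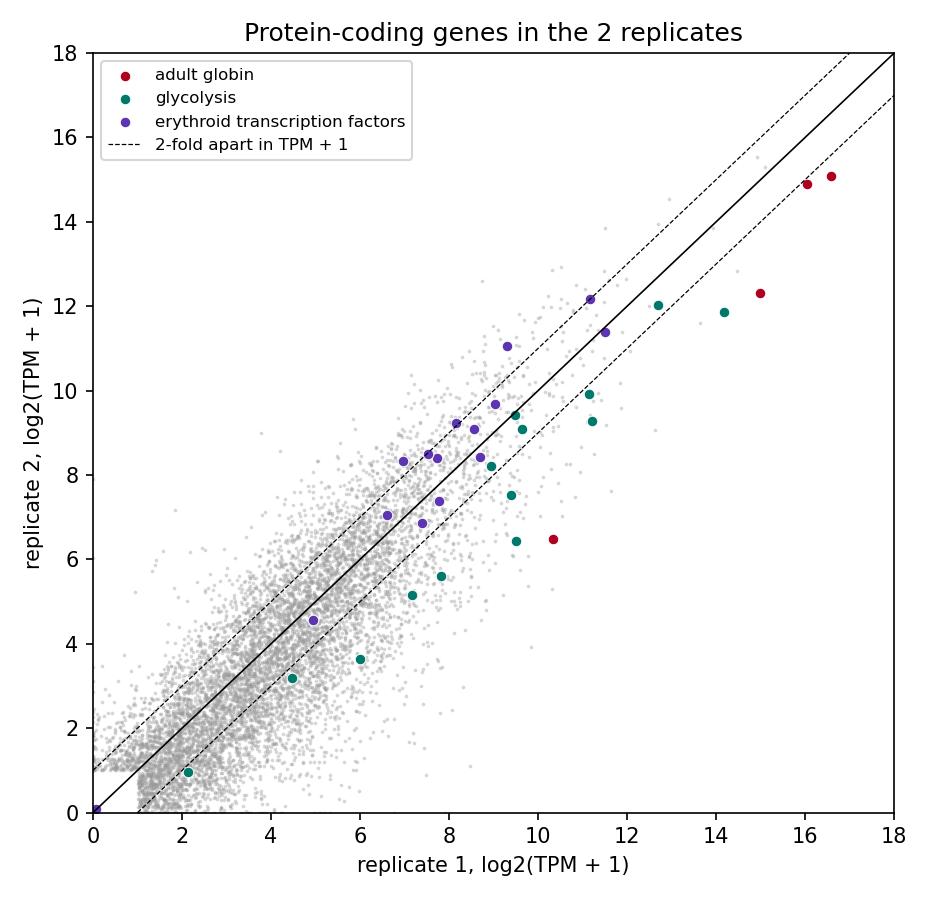
Each grey point is 1 protein-coding gene at 1 TPM or more in either replicate, with log2(TPM + 1) in replicate 1 on the horizontal and replicate 2 on the vertical axis, and coloured points are adult globin genes, glycolysis genes and erythroid transcription factors. The solid line marks equal values and the dashed lines a 2-fold difference in TPM + 1, and the 4 adult globin genes lie below the lower dashed line.

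By the log2 ratio of TPM + 1, the protein-coding genes with the largest difference toward replicate 1 were mt-Atp6, Cox17, mt-Nd4l, Atp5h and Gm11808. mt-Atp6 and mt-Nd4l, from the mitochondrial genome, had 9201 and 1139 expected counts in replicate 1 and 0 in replicate 2. The authors' intervals were 199 to 319 TPM in replicate 1 and up to 66.7 TPM in replicate 2 for mt-Atp6, and 57.3 to 160 TPM and up to 96.8 TPM for mt-Nd4l. Those of mt-Nd4l overlap, and no fold is given for either gene. Cox17 was at 353 and 1.14 TPM, a ratio of 39.5 in CPM as its effective length differed between replicates, and Gm11808 was at 172 and 1.88 TPM. Atp5h had 3628 and 3 expected counts, a ratio in CPM of 239 with an exact binomial 95% interval of 81.7 to 1159, for counting error only. In the other direction stood Gm49450, Gm44973, Gm10801, Gm10800 and the integrin gene Itga7. Gm49450 and Gm44973 had 0 counts in replicate 1 and 2274 and 698 in replicate 2. The authors' intervals reached 0.72 and 0.378 TPM in replicate 1 and began at 212 and 49.3 TPM in replicate 2. Gm10801 was at 2.56 and 144 TPM, Gm10800 at 12.6 and 512 TPM, and Itga7 at 1.99 and 72.8 TPM, a ratio of 14.3 in CPM.

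Replicate ratios varied with GC content. The median log2 ratio of TPM + 1 was -0.58 in the lowest of 10 bins of GC content and 0.49 in the highest, with Spearman's rho of 0.19 across 8485 genes. After removal of that trend, the medians were -2.27 for adult globin or -1.86 with the alpha genes summed, -1.24 for glycolysis and -1.16 for housekeeping genes.

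**Figure D3:**
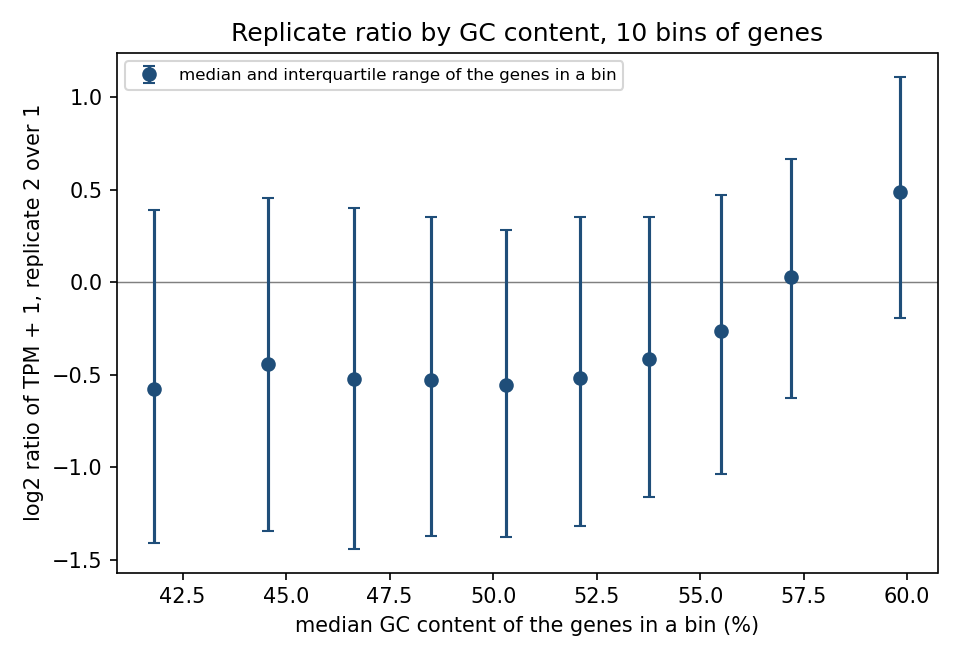
Points are medians and bars interquartile ranges of the log2 ratio of TPM + 1, replicate 2 over 1, in 10 bins of protein-coding genes ordered by the GC content of their transcripts in percent. The median lies between -0.58 and -0.42 in the 7 bins of lowest GC content and reaches 0.49 in the highest.

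Leading transcripts were the same in both replicates for 7 of the 12 genes examined, against 9 with annotation M4 and 10 in the transcript table quantified from reads. Klf1 is in these counts, and with 1 transcript annotated in M21 its match under that annotation was fixed in advance. The leading transcript held 99.99% and 100% of Gata1 TPM (ENSMUST00000033502.13), 94.8% and 99.8% of Bcl2l1 TPM, 95.1% and 96.7% of Pkm TPM, and 84.7% and 96.9% of Xpo7 TPM, while Klf1 has 1 annotated transcript. It held 65.3% and 68.7% of Tal1 TPM, and 61.8% and 70.0% of the TPM of Slc25a37, a mitochondrial iron importer gene, where it is annotated as subject to nonsense-mediated decay. In the table quantified from reads that Slc25a37 transcript held 38.8% and 11.7%. The leading transcript differed between replicates for the others, among them Alas2, Epb41, Ank1 and Lmo2. An Alas2 transcript annotated without a coding sequence (ENSMUST00000142474.1) held 73.4% of Alas2 TPM in replicate 1 and 1.45% in replicate 2. An Epb41 transcript of the same kind (ENSMUST00000146021.7) held 83.0% and 15.4% of Epb41 TPM, but 68.3% and 67.4% in the table quantified from reads. Across the 12 genes, Klf1 included, the median share of the leading transcript, averaged over both replicates, was 66.4%.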

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

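Only the Poisson simulation below was set up before its result was seen, and the other tests were chosen after the result was seen. The labels give 1 group, so the design offers no biological explanation for a difference between replicates and none was tested by it.

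The table quantified from reads held a signal that the comparisons do not use and that the main table lacks. The 3 genes Gm23935, Gm24270 and Gm24245, each annotated with the same 57-base microRNA sequence on chromosomes 16, 9 and 4, together held 18.7% of TPM there in replicate 1 and 72.6% in replicate 2, against 0 TPM in the main table and above the 3 counts that a count of 0 allows. The whole sequence is not part of a longer annotated transcript (0 were found). Only matches to the whole sequence were searched. A shorter or inexact match, or a source outside the annotation, would give the same result, so this search does not decide where the fragments came from. The share of estimated fragments was at most 0.025 of the share of TPM in either replicate. TPM divides fragments by effective length, here 11.2 and 7.94 bases, so this ratio follows from the formula and does not test where the signal comes from. Where the 260948 and 581418 estimated fragments came from stays open.

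The 4600 genes over 2-fold apart between the replicates far exceeded counting error, for which 20 simulations gave at most 18. Among the 8889 genes with a GC value and TPM above 0 in both, 4463 were over 2-fold apart before and 4353 after removal of the GC trend, 3840 of them in both, which argues against that trend as the whole cause. CPM, which uses no length, gave 4604, which argues against effective lengths as the whole cause. A difference between cultures, library preparations or RNA quality stays open, and none of these was tested.

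The lower globin share of replicate 2 was not explained by the GC trend, as the adult globin median stayed at -2.27 on the log2 scale with it removed, or at -1.86 with the alpha genes summed. The globin share of replicate 1 was 2.82 times that of replicate 2 in the main table, 2.74 times once rescaled over nuclear protein-coding genes, 5.34 times in the table made from reads and 1.72 times in that table rescaled the same way. Loss of fragments in the alignment-based tables may account for part of the difference by the rescaled values alone, and it stays open. An earlier erythroid stage in replicate 2 cannot be told apart from the rest, since the higher of the heme synthesis and membrane percentiles was 24.35 with the GC trend removed, while heme synthesis lay at 2.04 with TMM, 2.39 with DESeq2 and 1.94 in CPM, membrane genes at 0.76 in the rescaled table made from reads, and early progenitor genes at 97.85 with the GC trend removed. The condition on the progenitor list was added to this test after its value was seen.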

How the results depend on the processing

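The alternatives with CPM, with the GC trend removed, with the median ratio set to 0, with the alpha globin genes summed and with the read-based table over nuclear protein-coding genes were chosen after seeing the data. For the main results, without the values that leave out a replicate, 34 under planned and 14 under added alternatives lay within 1 SD of the 2 replicates, 1.5 times for a count or 0.01 for a correlation, and 18 and 6 did not. The bounds of 1 SD depend on how far apart the 2 replicates lay. For the globin share the SD was 9.06, so 5.84% in CPM still lay within the bound. For the alpha to beta ratio it was 0.00954, so small moves lay outside. With M4 in place of M21, Gata1 was at 2989 TPM, the alpha to beta ratio 0.832, the erythroid minus other-lineage level 6.48, the lists outside the percentiles of shift 5 and the median leading transcript share 77.9%. In the read-based table summed per gene, Gata1 was at 1299 TPM, the alpha to beta ratio 0.502, the erythroid minus other-lineage level 5.53, Pearson's r 0.887 and the genes over 2-fold apart 7922, and in its transcripts the median leading share was 75.8%. Over nuclear protein-coding genes that table gave Gata1 at 2448 TPM, a ratio of 0.502 and r of 0.898. In CPM Gata1 was at 4626, the alpha to beta ratio 0.935 and 7 lists lay outside. CPM and TPM are different units for a single gene. The Gata1 value in CPM is counted among the 6 above that did not hold, but it says nothing about the stability of its level. The posterior mean gave an embryonic share of 0.0255%. TMM scaling put 7 lists outside and DESeq2 size factors 8, against 3 in TPM. Both use counts without length correction. CPM, with neither factor, already gave 7, so the move goes with the change from TPM to such counts rather than with the factors. Pseudocount 0.1 gave an erythroid minus other-lineage level of 9.96 and r of 0.812, no filter r of 0.939, and 5 TPM in either replicate r of 0.775. Rescaling the read-based table, where 3 short genes hold 18.7% and 72.6% of TPM, brought the erythroid minus other-lineage level to 6.74, so its denominator accounts for that move and for part of that of Gata1. The cause of the remaining moves was not tested. Without either replicate in turn, the ranges were 2661 to 2890 TPM for Gata1, 7614 to 8171 genes detected, 7.04% to 19.8% for the globin share, 1.00 to 1.02 for the alpha to beta ratio, 0.00626% to 0.0127% for the embryonic share, 12 to 13 lists at or above the 95th percentile, 6.58 to 6.73 for the erythroid minus other-lineage level and 76.0% to 78.2% for the leading transcript share. The main leading transcript share of 66.4% lay below that range. It is a median over genes of shares averaged over both replicates, so it need not lie between the medians of single replicates. Glycolysis lay outside the percentiles of shift in 8 of 8 alternatives, as did adult globin with its alpha genes taken singly, against 4 of 8 with them summed. Summed, 2 lists lay outside in TPM. Housekeeping was outside in 7 of 8, its 2.68th percentile in the rescaled read-based table being the exception, while early progenitor genes were outside in 7 of 8. The 14121747 counts of replicate 2 allow up to 0.212 CPM for a gene with 0 counts there.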

Other observations

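The test on GC content and the gene groups below were chosen after the values were seen. Replication-dependent histone genes, which make mRNAs that mostly lack a poly(A) tail, had 52 of 67 protein-coding members detected and held 3.78% of TPM in replicate 1 and 4.24% in replicate 2. A few H2A genes held most of this, with Hist1h2ap at 22719 and 7318 TPM, Hist1h2ah at 6576 and 15770 TPM, and Hist1h2af at 2919 and 14717 TPM, and these near-identical copies can trade reads. Cytosolic ribosomal protein genes, 78 of 83 detected, held 10.3% and 5.42% of TPM. The 13 mitochondrial mRNAs, 9 of them detected, held 0.306% and 0.227% of TPM. Gm26917 and Gm42418 together held 1.35% and 3.67% of TPM, and 2.72% and 6.46% of expected counts.

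The deposited totals also differed by table. The read-based table held 99236349 estimated fragments in replicate 1 and 31979129 in replicate 2, 1.39 and 2.26 times the expected counts of the main table. The largest excess of fragments in replicate 2 was that of Gm42418, at 1.49 and 4.94 times the main count in replicates 1 and 2. Hbb-bs followed at 1.60 and 5.06 times, then Gm26917 at 1.98 and 2.57 times. For mt-Nd2 the ratios were higher, at 6.37 and 24.1 times, on fewer fragments.

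Several erythroid genes with low GC content were at low levels, and a candidate explanation is that GC content bears on the measured level. Across 46 members of the heme synthesis, membrane and late erythroid lists, GC content and mean log2(TPM + 1) correlated with Spearman's rho of 0.313 and Pearson's r of 0.321, or 0.290 without the 2 genes furthest from the median GC content. The relation is across genes, which are not independent replicates, and rho was 0.254 over 21951 protein-coding genes, so it is not particular to erythroid genes. It was first seen in these 46 genes, so its test on them restates it and leaves the explanation open. It does not separate a bias of the libraries from a real relation between GC content and expression.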
